A study of Homo sapiens with 16 samples.

How the data were processed

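Polyadenylated RNA was sequenced from 16 libraries of a pair of human clear cell renal carcinoma lines. The 786-O line, with its SETD2 gene intact (WT) or knocked out (KO), had been treated for 72 h with DMSO, the vehicle, or with 100 nM A1331852, an inhibitor of the pro-survival protein BCL-XL, with 3 libraries in each of the 4 groups. The A498 line was labelled SETD2 deficient or SETD2 add-back, with 2 libraries each. Groups, replicate numbers and batches were taken from the labels. Batch 1 held replicate 3 of each DMSO group and all 6 A1331852 libraries, batch 2 held replicates 1 and 2 of each DMSO group, and batch 3 held A498. Batch and treatment therefore overlapped in part, since batch 2 held DMSO libraries only.

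The deposited values were counts, 1 table per library, in which the authors had counted fragments per gene with featureCounts version 1.5.0-p3 on uniquely placed STAR alignments (reverse-stranded setting 2, exons summed by gene name, GENCODE release 41, GRCh38). Each table held 60606 gene names. Of these, 19391 were annotated as protein-coding by a match of names to GENCODE release 29 or RefSeq. These held 36623 and 39403 of the names. The submitters also named MultiQC 1.7 and DESeq2 among their tools, and any normalised table was not used here. The total count per library ran from 14172118 to 36037616. Precision was taken from the spread between libraries. Counting intervals (95%, exact binomial) and floors (3 counts over the group) covered counting error only, because no molecular identifiers were used.

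Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, the low-count filter of edgeR by group (minimum count of 10), a quasi-likelihood F test, and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p under 0.05 as the threshold for a call. The 12 libraries of 786-O were fitted together with batch as a term. The 4 libraries of A498 were fitted apart, and all 16 together for the difference between lines. The 4 comparisons within 786-O were KO against WT in DMSO, KO against WT in A1331852, and A1331852 against DMSO in WT and in KO cells, and the difference between those responses was tested as an interaction. In A498, deficient was compared with add-back. Shared calls of both lines were tested per direction by Fisher's exact test, two-sided. Nothing in the labels states that replicates were separate cultures, so p-values measure only the spread between these libraries, which is possibly technical in part. Between replicates 1 and 2 of a DMSO group the mean chi-square per gene was 4.05 in WT and 3.44 in KO cells, against 1 expected from sampling noise (medians 1.1 and 1.01, against 0.455), and it was 106 to 149 in pairs with replicate 3. Between A1331852 libraries of 1 group, all of batch 1, it was 26.3 to 108, and highest in the pairs of WT replicate 3 (108 and 74.5, against 27.8 for WT replicates 1 and 2). This does not tell separate cultures from separate preparations of 1 culture.

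A total of 29 gene lists (704 entries) covering interferon and nucleic acid sensing, cell death, mitochondria, metabolism, stress, cell cycle, chromatin and markers of other cell types was tested in each comparison with limma 3.58.1 camera on log2 CPM (prior count of 2, preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists with at least 3 tested members), and again with an estimated correlation. None of the 77 list calls held with an estimated correlation. Median, mean and test had the same sign in all 77 called lists, and differed in sign in 25 of the 113 list tests that were not called. The lists were also tested with limma fry, which does not compare a list with other genes, as directional and as mixed (both directions allowed). Directional fry called 0 lists for A1331852 in WT cells and for the difference of responses, and 5 to 11 in each other comparison. Groups, comparisons, lists, most alternatives and the rule for named genes were chosen before the data were examined. That rule took, per comparison, (a) SETD2, BCL2L1, MCL1, BCL2, BCL2L11, BAX, BAK1, CGAS, STING1 and IFNB1, (b) the 8 largest rises and 8 largest falls (5 and 5 for difference tests) among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the groups within any batch that held both (not asked of difference tests), and (c) per list up to 4 called members with the smallest adjusted p. The examples printed were picked from the genes of this rule after their values were seen, preferring those whose call held with each library left out. IFNB1 had too few counts to be tested. Some genes of the rule are not reported here.

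Replicate numbers were checked as pairs. Library residuals of the same number correlated between WT and KO at 0.569 to 0.765 in DMSO and 0.271 to 0.506 in A1331852, and at -0.0465 to 0.0542 between DMSO and A1331852. Replicates 1 and 2 of DMSO could not be told apart as pairs (0.601 between unlike numbers against 0.569). Batch was not removed from these residuals, and in both genotypes DMSO replicate 3 was of another batch than 1 and 2. The DMSO correlations could therefore come from batch alone and are no evidence of pairs. The numbers were taken as pairs between genotypes within a treatment, and fits with a replicate block were run as alternatives. In 786-O this block also joined the same numbers across treatments, although they did not pair libraries there. Only a block within treatment, added after the data were seen, kept to the pairs as taken. The other alternatives were limma voom, DESeq2 1.42.0, DESeq2 and upper-quartile size factors, no filter and a filter at a mean of 50 counts, thinning to the smallest total, no batch term, single batches, the compared libraries alone, an added log2 threshold of 1, and each library left out in turn. The tests were also tested on simulated counts, drawn gene by gene from the count model that edgeR fitted to these libraries, with group effects removed. Seeded 2-fold changes were recovered at 23% (difference between lines) to 79.6% (A498), and 4-fold changes at 73% to 98%. By edgeR and voom 3.9% to 8.57% of calls were false. By DESeq2 19.1% of calls were false for KO against WT in DMSO and 2.89% in A498. These shares hold under that model, with few genes changed and no correlation between genes.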

Results

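Transcript levels were measured in 16 libraries, 12 from 786-O and 4 from A498, both established lines of clear cell renal carcinoma that lack functional VHL. SETD2 encodes the methyltransferase that places trimethyl marks on lysine 36 of histone H3 and is often lost in this cancer. The 786-O libraries came as 4 groups of 3: SETD2 WT and SETD2 KO cells, each after 72 h in DMSO or in 100 nM A1331852, an inhibitor of BCL-XL, the anti-apoptotic protein encoded by BCL2L1. A498 gave 2 libraries labelled SETD2 deficient and 2 labelled add-back. The total count was 36037616, 29753887 and 15199420 in WT DMSO replicates 1 to 3, and 35834962, 33150599 and 18723416 in KO DMSO. It was 16988255, 21951773 and 16731360 in WT A1331852, and 18330094, 18087078 and 14172118 in KO A1331852. The A498 libraries held 16358468 and 16411606 counts (deficient) and 16841656 and 17811303 (add-back). Levels are in CPM (counts scaled to a common library total), changes are log2 fold changes ± standard error from edgeR, and intervals and floors cover counting error only.

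**Figure D1:**
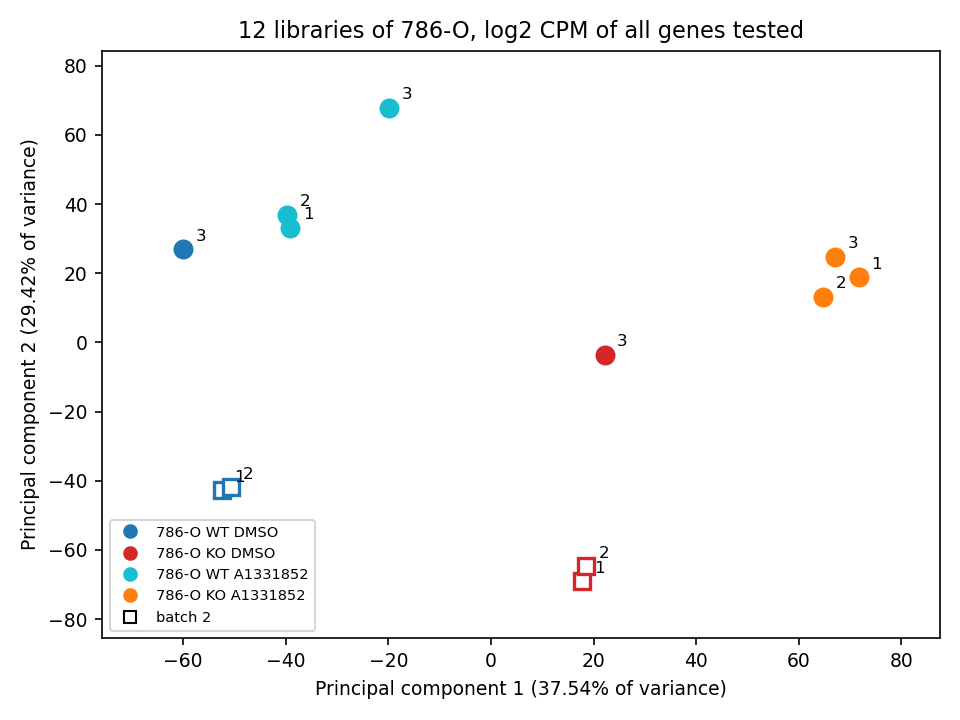
Principal components of log2 CPM in the 12 libraries of 786-O, with component 1 (37.5% of the variance) on the horizontal and component 2 (29.4%) on the vertical axis; each point is a library and its number the replicate. All 6 KO libraries lie above 0 and all 6 WT libraries below 0 on component 1.

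The first comparison asked what differs between SETD2 KO and WT 786-O cells treated with vehicle. As 1 KO and 1 WT population were studied, loss of SETD2 could not be separated from other differences between these populations. SETD2 (chromosome 3, 47016428 to 47164113, GRCh38) fell from 68.0 ± 2.67 CPM in WT to 29.4 ± 1.20 CPM in KO cells (SD, n = 3 each). Its log2 change was -1.21 ± 0.18, with an adjusted p of 7.39e-04 (edgeR quasi-likelihood, Benjamini-Hochberg). As groups, replication-dependent histone genes and interferon-stimulated genes were higher in KO cells, and genes of cytosolic ribosomal proteins and of glycolysis were lower. Most members of the last 3 lists were not called, and none of these list calls held with an estimated correlation. BAK1 (chromosome 6, 33572547 to 33580293), an effector that permeabilises the mitochondrial outer membrane, rose by 0.82 ± 0.12 on the log2 scale (adjusted p = 8.58e-04, edgeR). BCL2L1, the gene of the drug target, had a log2 change of -0.18 ± 0.19 (adjusted p = 0.583, edgeR), and MCL1, another anti-apoptotic gene, one of -0.40 ± 0.14 (adjusted p = 0.0615, or 0.0181 with a replicate block, edgeR).

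In all, 3001 of 16260 genes tested were called by edgeR between KO and WT cells in DMSO, 1348 higher and 1653 lower, where 813 would have an unadjusted p under 0.05 by chance and 5207 did. The larger share turned with an added log2 threshold of 1, to 754 higher and 519 lower, with upper-quartile factors, to 1586 and 1364, and without KO DMSO replicate 3, to 884 and 809. RTN1 (chromosome 14, 59595976 to 59870776), which encodes a reticulon of the endoplasmic reticulum, rose by 7.16 ± 0.34 (adjusted p = 3.56e-07, edgeR), from 0.0813 ± 0.0762 to 13.4 ± 3.15 CPM (SD, n = 3). SLAIN1 rose by 6.63 ± 0.43, SDK1, an adhesion molecule, by 4.90 ± 0.29, COL12A1, a collagen, by 4.65 ± 0.24 and DSP, a component of desmosomes, by 4.23 ± 0.45. The transcription factor gene POU3F3 had 643 counts in KO and 3 in WT cells, a ratio of 183 (95% counting interval 62.2 to 888). It was 103 without WT DMSO replicate 1 and at least 117 without replicate 2, which held all 3 WT counts. SORT1 (chromosome 1, 109309568 to 109397918), a sorting receptor of the Golgi, changed by -5.30 ± 0.24 (adjusted p = 2.02e-07, edgeR). C1QTNF1 changed by -5.72 ± 0.51, GLMP, a lysosomal membrane protein, by -5.19 ± 0.26, and SNAI2, a transcription factor of epithelial to mesenchymal transition, by -2.93 ± 0.27. SRGN, a proteoglycan of secretory granules, had 419 counts in WT and 1 in KO cells, so its level was higher in WT by a ratio of 492 (87.8 to 19500). It was 296 without KO DMSO replicate 1 and at least 103 without replicate 2. The neutrophil chemoattractants CXCL5 (-4.29 ± 0.33) and CXCL1 (-2.09 ± 0.38) fell, as 6 of 27 NF-kB targets did with none rising, although that list was not called (adjusted p = 0.218, camera).

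Of 13 replication-dependent histone genes tested, 10 rose and 0 fell in KO cells (11 and 0 adjusted over the list alone), with a median log2 change of 1.46 and an adjusted p of 1.31e-07 (camera), or 0.217 with an estimated correlation. As polyadenylated RNA was sequenced, the values of these genes here and below do not measure histone transcripts without a poly(A) tail. H2BC12 rose by 1.77 ± 0.17 and the linker histone gene H1-2 by 1.19 ± 0.16. Of 41 interferon-stimulated genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone). The median was 0.34, with an adjusted p of 2.67e-04, or 0.922 with an estimated correlation. OASL, an oligoadenylate synthetase-like antiviral protein, rose by 1.44 ± 0.25, IFITM3, which restricts viral entry, by 1.25 ± 0.24 and CMPK2, a mitochondrial nucleotide kinase, by 1.19 ± 0.22. Of 82 cytosolic ribosomal protein genes, 14 fell and 1 rose (17 and 2 adjusted over the list alone). The median was -0.26, with an adjusted p of 1.13e-05, or 0.922 with an estimated correlation, and RPS3 changed by -0.95 ± 0.13 and RPL8 by -0.67 ± 0.12. Of 23 glycolysis genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.25, adjusted p = 0.0333, or 0.403 with an estimated correlation). Members included ENO2 (-1.46 ± 0.27), PFKM (-1.07 ± 0.14) and HK1 (-0.62 ± 0.12). Of 26 p53 targets, 5 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.0341, or 0.922 with an estimated correlation). SPATA18 changed by -4.29 ± 0.31 and PHLDA3 by -0.87 ± 0.12, and DDB2 by 0.75 ± 0.15. Of 19 genes of MHC class I antigen presentation, 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.47, adjusted p = 0.0459, or 0.922 with an estimated correlation). PSMB8, an immunoproteasome subunit, rose by 0.55 ± 0.11. The p53 call was lost without replicate 3 of WT DMSO or KO DMSO (adjusted p up to 0.0612). The MHC call was lost without WT DMSO replicate 1 or 3 or KO DMSO replicate 2 or 3 (up to 0.117). With a filter at a mean of 50 counts the glycolysis and p53 calls were lost (0.0559 each). Among markers of other cell types, CD14 rose by 2.95 ± 0.38, to 1.00 CPM, and LUM, a fibroblast gene, changed by -1.87 ± 0.22. The list of leukocyte genes was not called (median -0.212, mean 0.633, adjusted p = 0.479, camera).

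The count of 3001 genes fell when any DMSO library was left out: to 1777 and 1693 without WT and KO replicate 3, to 1615 and 1653 without WT replicates 1 and 2, and to 1673 and 1614 without KO replicates 1 and 2 (edgeR). Batch 2 alone gave 9276 genes, a replicate block 4862 (4646 within treatments), and batch 1 held 1 library per genotype in DMSO. KO minus WT differences in the batches correlated across genes at Pearson r = 0.745 (Spearman rho = 0.638; genes are not independent replicates).

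**Figure D2:**
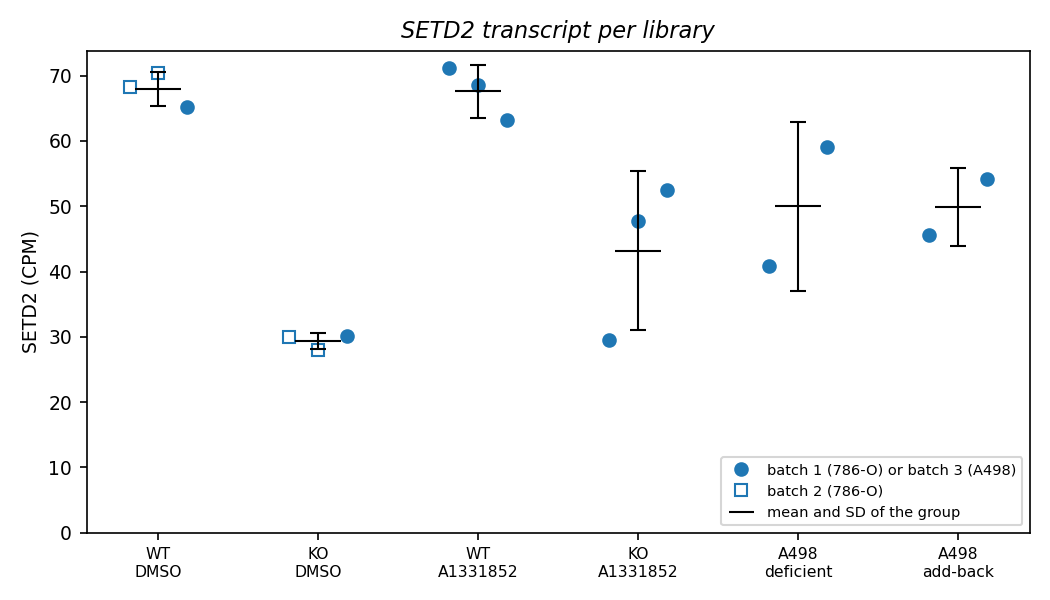
SETD2 level in CPM (vertical axis, from 0) in each of the 16 libraries by group; points are libraries and bars the group mean and SD. KO DMSO libraries lie at 28.0 to 30.2 CPM, WT libraries at 63.2 to 71.1, and both A498 arms overlap.

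The second comparison asked what differs between KO and WT cells under the BCL-XL inhibitor, with the same limit of 1 population per genotype. Interferon-stimulated genes were higher in KO than in WT cells as a group, along with genes of antigen presentation, and mRNAs of the mitochondrial genome were lower, though none of these list calls held with an estimated correlation. OASL (chromosome 12, 121017763 to 121039246) rose from 5.57 ± 1.02 CPM in WT (SD, n = 3) to 106 CPM in KO cells (n = 3, range 96.7 to 119.5). The log2 change was 4.25 ± 0.26, with an adjusted p of 1.71e-06 (edgeR). SETD2 itself was at 67.6 ± 4.03 CPM in WT and 43.2 ± 12.1 CPM in KO cells, a log2 change of -0.65 ± 0.18 (adjusted p = 0.0168, edgeR). BAK1 rose by 1.25 ± 0.13 (adjusted p = 3.98e-05, edgeR), and BCL2L1 had a change of 0.04 ± 0.19 (adjusted p = 0.905, edgeR).

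A total of 4588 of 16260 genes were called by edgeR, 2150 higher and 2438 lower in KO than in WT cells under A1331852 (957 and 948 with an added log2 threshold of 1), all 6 libraries being in batch 1. COL12A1 rose by 5.79 ± 0.29, DSP by 5.84 ± 0.55 and CLGN, a chaperone of the endoplasmic reticulum, by 7.36 ± 0.36. CDH4, a cadherin, had 697 counts in KO and 1 in WT cells, a ratio of 742 (133 to 29300), or 450 without WT A1331852 replicate 2 and at least 169 without replicate 1. RTN1 had 500 and 1, a ratio of 532 (95.1 to 21100), or at least 108 without WT A1331852 replicate 2. SLAMF7, a receptor of immune cells, had 873 and 3, a ratio of 310 (106 to 1500), or 564 without that library. SORT1 changed by -6.04 ± 0.27, MCAM, an adhesion molecule, by -5.44 ± 0.22, SYT11 by -5.51 ± 0.46 and SPATA18 by -5.77 ± 0.38. CDH16, the kidney-specific cadherin, changed by -2.85 ± 0.25, LUM by -2.70 ± 0.24.

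Under A1331852, 36 of 41 interferon-stimulated genes rose in KO relative to WT cells and 0 fell (37 and 0 adjusted over the list alone). The median was 1.91, with an adjusted p of 4.26e-19 (camera), or 0.416 with an estimated correlation. CMPK2 rose by 3.71 ± 0.23, ISG20, an RNA exonuclease, by 3.38 ± 0.25 and IFI44 by 2.34 ± 0.18. Of 20 genes of cytosolic nucleic acid sensing, 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.34, adjusted p = 0.00414, or 0.416 with an estimated correlation). The RNA sensor gene IFIH1 changed by 1.89 ± 0.24, the nucleotide hydrolase gene SAMHD1 by 1.68 ± 0.22 and the adaptor gene MAVS by -0.79 ± 0.11. CGAS, the cytosolic DNA sensor, rose by 0.62 ± 0.17 (adjusted p = 0.0203, edgeR), a call lost without WT A1331852 replicate 2 (0.0568) or KO A1331852 replicate 1 (0.0588) or 2 (0.0654). Of 19 genes of MHC class I presentation, 12 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.64, adjusted p = 3.91e-05, or 0.416 with an estimated correlation). Members included PSME2 (1.20 ± 0.14), NLRC5 (1.17 ± 0.16) and PSMB8 (0.93 ± 0.11). Of 27 NF-kB targets, 10 rose and 2 fell (10 and 3 adjusted over the list alone; median 0.44, adjusted p = 0.00795, or 0.778 with an estimated correlation), a call lost without WT A1331852 replicate 1 (0.0615). TNFAIP3, an inhibitor of NF-kB, rose by 1.69 ± 0.24, the cytokine gene IL6 by 1.52 ± 0.21 and the collagenase gene MMP1 by 4.19 ± 0.47, and CXCL5 changed by -3.33 ± 0.37.

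Of the 13 mRNAs of the mitochondrial genome, 9 fell and 0 rose in KO relative to WT cells under A1331852 (10 and 0 adjusted over the list alone; median -0.68, adjusted p = 2e-04, or 0.498 with an estimated correlation). MT-CO1 changed by -1.34 ± 0.17 and MT-ND6 by -1.02 ± 0.22. Of 25 cholesterol synthesis genes and SREBP targets, 10 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.49, adjusted p = 0.00158, or 0.778 with an estimated correlation). LSS changed by -1.94 ± 0.37, ACACA by -1.12 ± 0.23 and MVD by -0.72 ± 0.12. Of 26 p53 targets, 10 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.33, adjusted p = 0.00462, or 0.425 with an estimated correlation). Members included RRM2B (-1.55 ± 0.19) and XPC (-0.96 ± 0.16). Of 13 histone genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone; median 1.32, adjusted p = 1.43e-04, or 0.416 with an estimated correlation). H2BC12 changed by 1.96 ± 0.18 and H2BC5 by 1.72 ± 0.24. Mitochondrial ribosomal protein genes (16 of 77 rose and 6 fell, 16 and 6 adjusted over the list alone; median 0.24, adjusted p = 0.0305, or 0.861 with an estimated correlation) included MRPS34 (0.88 ± 0.14) and MRPS21 (-0.89 ± 0.11). Cytosolic ribosomal protein genes (18 of 82 fell and 4 rose, 18 and 3 adjusted over the list alone; median -0.17, adjusted p = 0.0151, or 0.861 with an estimated correlation) included RPS3 (-0.83 ± 0.13) and RPL22L1 (1.58 ± 0.20). The mitochondrial ribosomal call was lost without WT A1331852 replicate 3 or KO A1331852 replicate 1 (up to 0.491), or without a batch term (0.0506). The cytosolic call was lost without WT A1331852 replicate 3 or KO A1331852 replicate 2 or 3 (up to 0.36), or both A1331852 replicates 3 (0.972). BMF, a pro-apoptotic BCL-2 family gene, changed by -2.51 ± 0.39.

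**Figure D3:**
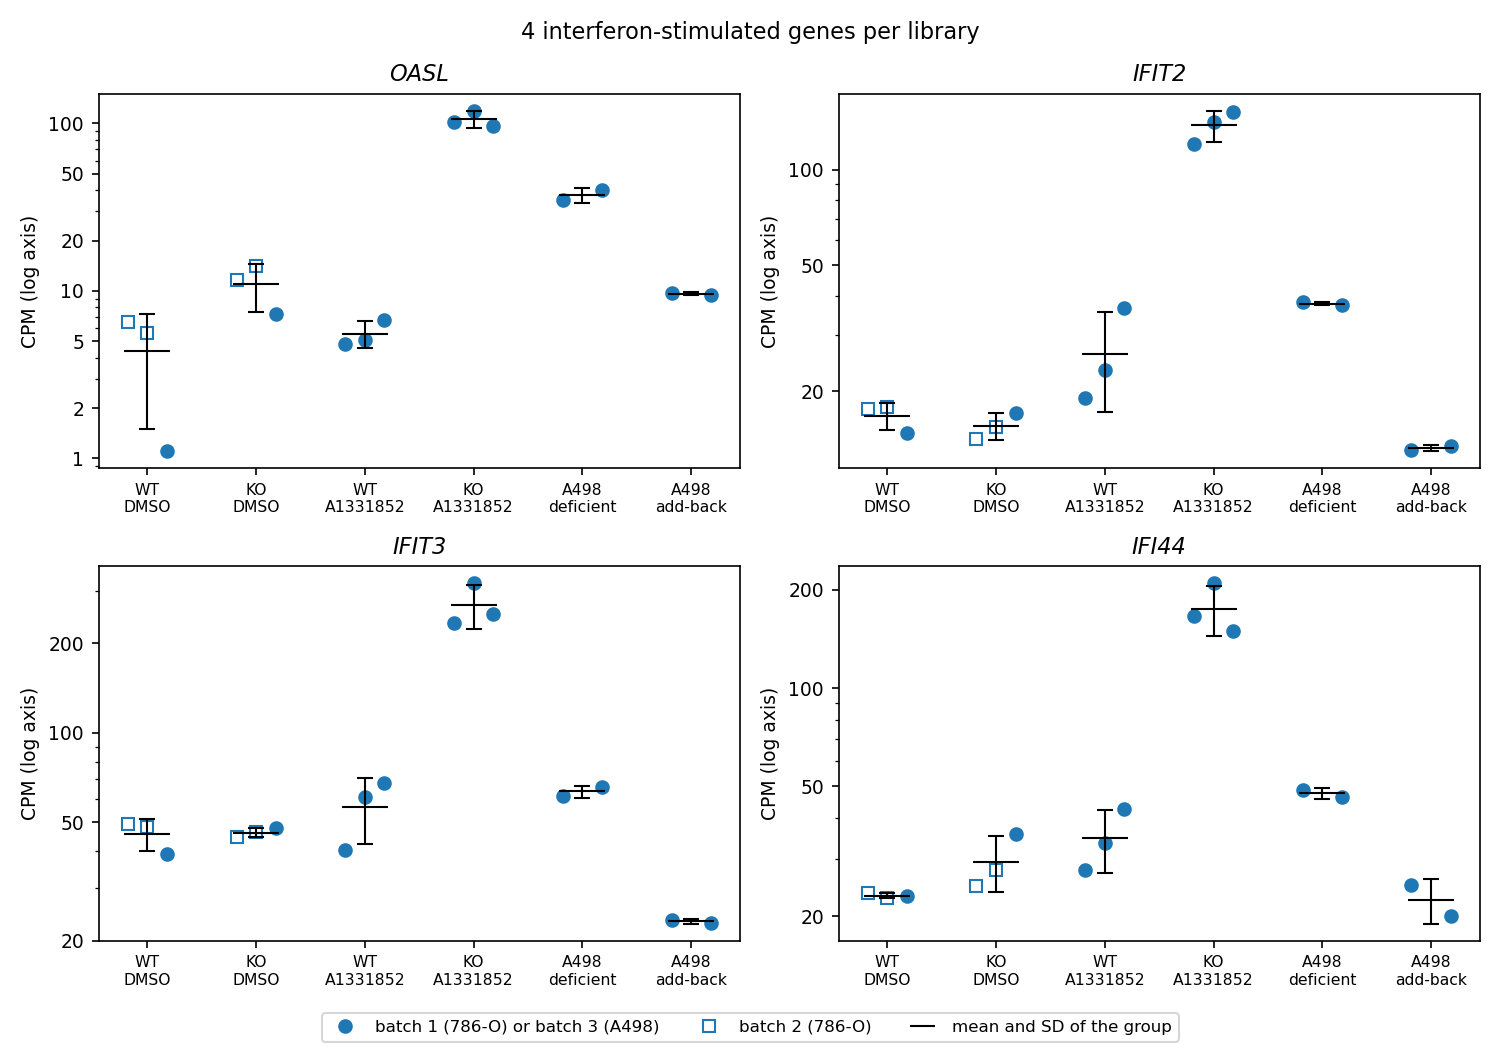
Levels in CPM (vertical axis, log scale) of the interferon-stimulated genes OASL, IFIT2, IFIT3 and IFI44 in each library by group; filled circles are batches 1 and 3, open squares batch 2, and bars the group mean and SD. KO A1331852 libraries lie above the other 9 libraries of 786-O for OASL.

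The third comparison asked how WT 786-O cells respond to A1331852. The ETS transcription factor gene ETV1 (chromosome 7, 13891229 to 13991425) rose by 2.12 ± 0.22 (adjusted p = 0.00714, edgeR, n = 3) and its relative ETV5 by 2.12 ± 0.31. AMIGO2, an adhesion molecule, rose by 1.29 ± 0.15, UBASH3B, a tyrosine phosphatase, by 1.59 ± 0.24 and SNTB1, a syntrophin, by 1.08 ± 0.16. SAA1, an acute-phase protein, changed by -2.67 ± 0.38 (adjusted p = 0.0244, edgeR), C1orf116 by -2.27 ± 0.32, SUSD4 by -1.87 ± 0.29, and the tubulin gene TUBA1A by -1.65 ± 0.24. The transporter genes ABCC9 and ABCB1 changed by -1.43 ± 0.21 and -1.37 ± 0.19, L1CAM by -1.22 ± 0.19, the small heat shock protein gene HSPB8 by -1.19 ± 0.20 and COL8A1 by -0.91 ± 0.13. SETD2 had a log2 change of 0.00 ± 0.21 (adjusted p = 0.996, edgeR) and BCL2L1 one of 0.19 ± 0.24 (adjusted p = 0.792, edgeR). Of 16260 genes tested, edgeR called 23, 6 higher and 17 lower, against 26 with limma voom, 415 with DESeq2 and 2080 at an unadjusted p under 0.05. By chance 813 would have such a p. Without WT DMSO replicate 3, 596 of 16770 genes had an unadjusted p under 0.05, fewer than by chance. This is the WT DMSO library of the batch that held the treated libraries, and without it edgeR called 0 genes. Without WT DMSO replicate 1 or 2 it called 3 each (adjusted p of HSPB8 0.106 and 0.0968), and without WT A1331852 replicate 1, 2 or 3 it called 64, 45 and 48. More genes were higher than lower without WT A1331852 replicate 1 (41 and 23), without WT DMSO replicate 1 or 2 (2 and 1 each) and by DESeq2 (223 and 192). Within batch 1 alone, with 1 DMSO library per genotype whose spread was assumed to be that of the other groups, edgeR called 0 genes (1351 at an unadjusted p under 0.05), and without replicate 3 of both A1331852 groups it called 214.

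In WT cells, cell cycle genes and targets of hypoxia-inducible factors were higher and cholesterol synthesis genes lower as groups after A1331852, though edgeR and voom called 0 members of each over all genes. Directional fry called 0 of 27 lists in this comparison. Of 45 cell cycle genes, 4 rose and 0 fell adjusted over the list alone (20 at an unadjusted p under 0.05, 4 by DESeq2). The median was 0.52, with an adjusted p of 3.69e-11 (camera), or 0.482 with an estimated correlation. Of 29 hypoxia-inducible factor targets, 3 rose adjusted over the list alone (12 unadjusted, 3 by DESeq2; median 0.56, adjusted p = 4.07e-05, or 0.576 with an estimated correlation). Of 25 cholesterol genes, 6 fell adjusted over the list alone (10 unadjusted, 2 by DESeq2; median -0.56, adjusted p = 4.4e-08, or 0.482 with an estimated correlation). The integrated stress response list (29 genes, 0 adjusted over the list alone, 9 unadjusted, 3 by DESeq2) had a median of 0.45 and an adjusted p of 1.68e-04, or 0.482 with an estimated correlation. Nuclear respiratory chain genes (76 genes, 0 adjusted over the list alone, 3 unadjusted, 1 by DESeq2) had a median of -0.20 and an adjusted p of 1.68e-04, or 0.708 with an estimated correlation. For the 41 interferon-stimulated genes the median was 0.12 (adjusted p = 0.631, camera), with 0 called by edgeR and voom, 2 by DESeq2 and 7 at an unadjusted p under 0.05. The cell cycle call was lost with a replicate block (0.275) and without a batch term (0.121), and without a batch term the stress response (0.109) and respiratory chain (0.959) calls were lost too. A further 7 list calls, among them DNA damage genes (adjusted p = 2.95e-05) and histones (0.00221), were lost without 1 library: DNA damage without WT DMSO replicate 3 (0.425) and histones without WT A1331852 replicate 2 (0.128). Both were also lost with a replicate block (0.241 and 0.275) and with an estimated correlation (0.482 each), histones without a batch term too (0.12).

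The fourth comparison asked how KO cells respond to the inhibitor. Interferon-stimulated genes, NF-kB targets and genes of the integrated stress response rose as groups, while cholesterol synthesis genes and mRNAs of the mitochondrial genome fell. Among markers of other cell types, the list of 3 leukocyte genes was higher as a group (median 2.14, adjusted p = 0.0187, camera). That of 5 fibroblast and pericyte genes was lower (median -0.93, 0.0309), though not every member was called. Both calls were lost when 1 library was left out, among others KO DMSO replicate 3 (up to 0.405 and 0.175). None of these list calls held with an estimated correlation. OASL rose by 4.23 ± 0.33 (adjusted p = 1.85e-04, edgeR, n = 3), or 5.47 without KO DMSO replicate 3. PMAIP1, which encodes the MCL1-binding protein NOXA, rose from 31.7 to 188 CPM, by 2.41 ± 0.28 (adjusted p = 6.94e-04, edgeR). BCL2L1 had a change of 0.40 ± 0.24 (adjusted p = 0.293, edgeR) and MCL1 one of 0.39 ± 0.17 (adjusted p = 0.144, edgeR). A replicate block gave called changes of 0.72 and 0.57, although the numbers did not pair libraries across treatments. SETD2 had one of 0.57 ± 0.22 (adjusted p = 0.105, edgeR), which was called at 0.79 without KO A1331852 replicate 1 (adjusted p = 0.00707).

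Of 16260 genes, 2201 were called by edgeR, 1050 higher and 1151 lower after A1331852 in KO cells (831 and 1363 with upper-quartile factors, 780 and 750 without KO A1331852 replicate 1, 2733 and 2494 without replicate 3 of both A1331852 groups, and 1566 and 1509 by DESeq2). MMP1 (chromosome 11, 102789401 to 102798160) rose by 6.76 ± 0.71, or 7.63 without KO DMSO replicate 3, and CLDN1, a tight junction protein, by 2.63 ± 0.48. SEMA5B, an axon guidance protein, changed by -5.16 ± 0.55 (-6.25 without KO DMSO replicate 3, -5.85 without KO A1331852 replicate 3), the immediate early gene EGR1 by -4.98 ± 0.88 and the apical scaffold gene PDZK1 by -4.94 ± 0.57. The kidney cadherin genes CDH16 and CDH6 changed by -3.33 ± 0.29 (-3.93 without KO DMSO replicate 3) and -1.94 ± 0.36. In the BCL-2 family, BID rose by 0.95 ± 0.18 and BMF changed by -2.89 ± 0.45 (-3.89 without KO DMSO replicate 3). BCL2 changed by -1.12 ± 0.29 (adjusted p = 0.0276, edgeR), a call lost without KO DMSO replicate 3 (0.21) or 1 (0.0575) or KO A1331852 replicate 1 (0.0707). BCL2L11, which encodes the pro-apoptotic BIM, changed by -1.51 ± 0.41 (adjusted p = 0.0327, edgeR), lost without KO DMSO replicate 1 (0.0634), 2 (0.0648) or 3 (0.0647; log2 -2.12) or KO A1331852 replicate 1 (0.0929) or 2 (0.0685).

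In KO cells, 26 of 41 interferon-stimulated genes rose and 1 fell after A1331852 (30 and 2 adjusted over the list alone). The median was 1.23, with an adjusted p of 2.47e-13 (camera), or 0.341 with an estimated correlation. ISG20 rose by 3.53 ± 0.33, IFIT2, which binds foreign RNA, by 3.16 ± 0.28 and IFIT3 by 2.62 ± 0.24. Nucleic acid sensing genes (5 of 20 rose and 2 fell) were not called as a list (median 0.36, adjusted p = 0.0672). Among them the ubiquitin ligase gene TRIM25 rose by 1.15 ± 0.23. CGAS rose by 0.86 ± 0.21 (adjusted p = 0.0214, edgeR; 0.0549 without KO A1331852 replicate 2). Of 27 NF-kB targets, 10 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.97, adjusted p = 1.66e-05, or 0.437 with an estimated correlation). Members included IL6 (2.43 ± 0.28), CSF1, the macrophage growth factor (1.55 ± 0.20), and NFKBIZ (-1.46 ± 0.24). Of 29 integrated stress response genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.64, adjusted p = 3.53e-05, or 0.341 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, rose by 1.28 ± 0.27, a call lost without KO DMSO replicate 3 (0.19). Of 25 cholesterol genes, 17 fell and 0 rose (23 and 0 adjusted over the list alone; median -0.998, adjusted p = 1.05e-10, or 0.341 with an estimated correlation). LSS changed by -2.19 ± 0.42 (adjusted p = 0.112 without KO DMSO replicate 3).

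Of the 13 mRNAs of the mitochondrial genome, 10 fell and 0 rose after A1331852 in KO cells (13 and 0 adjusted over the list alone; median -0.84, adjusted p = 4.79e-07, or 0.341 with an estimated correlation). MT-CO1 changed by -1.15 ± 0.20. The share of all counts from the mitochondrial genome was 1.44% to 1.69% in KO A1331852 libraries, 2.98% to 3.77% in KO DMSO, 2.07% to 3.24% in WT A1331852 and 3.21% to 3.95% in WT DMSO libraries. DNA damage genes (5 of 31 rose and 0 fell, 5 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.00545, or 0.594 with an estimated correlation) were also called. So were genes of mitochondrial DNA maintenance (2 of 26 rose and 0 fell, 0 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.0228, or 0.341 with an estimated correlation). Both were lost with a replicate block (0.168 and 0.159) and without a batch term (0.0732 and 0.115). Another 9 list calls were lost when 1 library was left out. MHC class I genes (adjusted p = 0.0182) were lost without KO DMSO replicate 3 or KO A1331852 replicate 3 (up to 0.0787), and cell cycle genes (0.00929) without KO A1331852 replicate 1 (0.0887). Both were also lost without a batch term (0.526 and 0.627) and with an estimated correlation (0.581 and 0.777), cell cycle genes with a replicate block too (0.766).

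The count of 2201 fell to 781 without KO DMSO replicate 3, the KO DMSO library of the batch of the treated libraries, to 1303 and 1330 without KO DMSO replicates 1 and 2, and to 1411 without KO A1331852 replicate 2 (edgeR). Batch 1 alone, with 1 DMSO library per genotype, gave 85 genes, and leaving out replicate 3 of both A1331852 groups gave 5227.

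The fifth comparison tested whether the response to A1331852 differed between KO and WT cells. As groups, interferon-stimulated genes and NF-kB targets responded more in KO cells, although 9 of 41 and 2 of 27 members were called and neither list call held with an estimated correlation. Directional fry called 0 of 27 lists for this difference. The difference in log2 response was 2.81 ± 0.35 for OASL (adjusted p = 0.00736, edgeR, n = 3 per group), 2.50 ± 0.30 for IFIT2 (adjusted p = 0.00726, edgeR), 2.23 ± 0.26 for IFIT3 and 2.01 ± 0.25 for IFI44. It was 6.44 ± 0.67 for MMP1 (adjusted p = 0.00726, edgeR), 3.97 ± 0.58 for the Notch ligand gene DNER and 3.12 ± 0.38 for the keratin gene KRT81. It was 3.02 ± 0.51 for SERPINB7 and 1.77 ± 0.31 for IL6. It was -4.24 ± 0.61 for SEMA5B (-4.86 without KO DMSO replicate 3, -4.94 without KO A1331852 replicate 3), -3.86 ± 0.66 for PDZK1, -2.39 ± 0.43 for CD24, -2.32 ± 0.33 for NCKAP5 and -2.32 ± 0.33 for CDH16. For SETD2 it was 0.56 ± 0.25 (adjusted p = 0.438, edgeR). The edgeR test called 48 of 16260 genes, 33 with a higher and 15 with a lower response in KO cells (43 and 46 without KO DMSO replicate 3), against 44 with limma voom, 371 with DESeq2 and 1762 at an unadjusted p under 0.05. By chance 813 would have such a p.

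In the test of the difference, 9 of 41 interferon-stimulated genes had a larger response in KO cells and 0 a smaller one (27 and 0 adjusted over the list alone). The median was 1.48, with an adjusted p of 2.27e-25 (camera), or 0.474 with an estimated correlation. Of 27 NF-kB targets, 2 were called higher (9 adjusted over the list alone; median 0.96, adjusted p = 4.36e-09, or 0.474 with an estimated correlation). In 4 further lists edgeR called 0 members over all genes. For mRNAs of the mitochondrial genome, 8 of 13 were lower adjusted over the list alone (9 at an unadjusted p under 0.05, 2 by DESeq2; median -0.65, adjusted p = 3.75e-07, or 0.474 with an estimated correlation). For cholesterol genes, 1 of 25 was lower adjusted over the list alone (4 unadjusted, 1 by DESeq2; median -0.49, adjusted p = 5.48e-05, or 0.683 with an estimated correlation). For MHC class I genes, 4 of 19 were higher adjusted over the list alone (6 unadjusted, 2 by DESeq2; median 0.26, adjusted p = 1.31e-04, or 0.561 with an estimated correlation). For nucleic acid sensing genes, 2 of 20 were higher adjusted over the list alone (5 unadjusted, 2 by DESeq2; median 0.35, adjusted p = 0.016, or 0.474 with an estimated correlation).

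Without KO DMSO replicate 1 or 2, edgeR called 0 genes for the difference (1186 and 1159 at an unadjusted p under 0.05; OASL at 0.0526 and 0.0646 adjusted). It called 10 without WT DMSO replicate 1 or 2, 15 without KO A1331852 replicate 2, 24 and 31 without WT A1331852 replicates 2 and 1, and 87, 89 and 5.0e+02 (rounded) without WT DMSO 3, KO DMSO 3 and WT A1331852 3 (adjusted p of CD24 up to 0.216). The library WT A1331852 replicate 3 lay apart from replicates 1 and 2, at 67.9 on principal component 2 against 33.1 and 36.9. A replicate block gave 334 genes or, within treatments, 294, and leaving out replicate 3 of both A1331852 groups gave 929. The fit of batch 1 alone rested on 1 DMSO library per genotype and is not counted here.

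**Figure D4:**
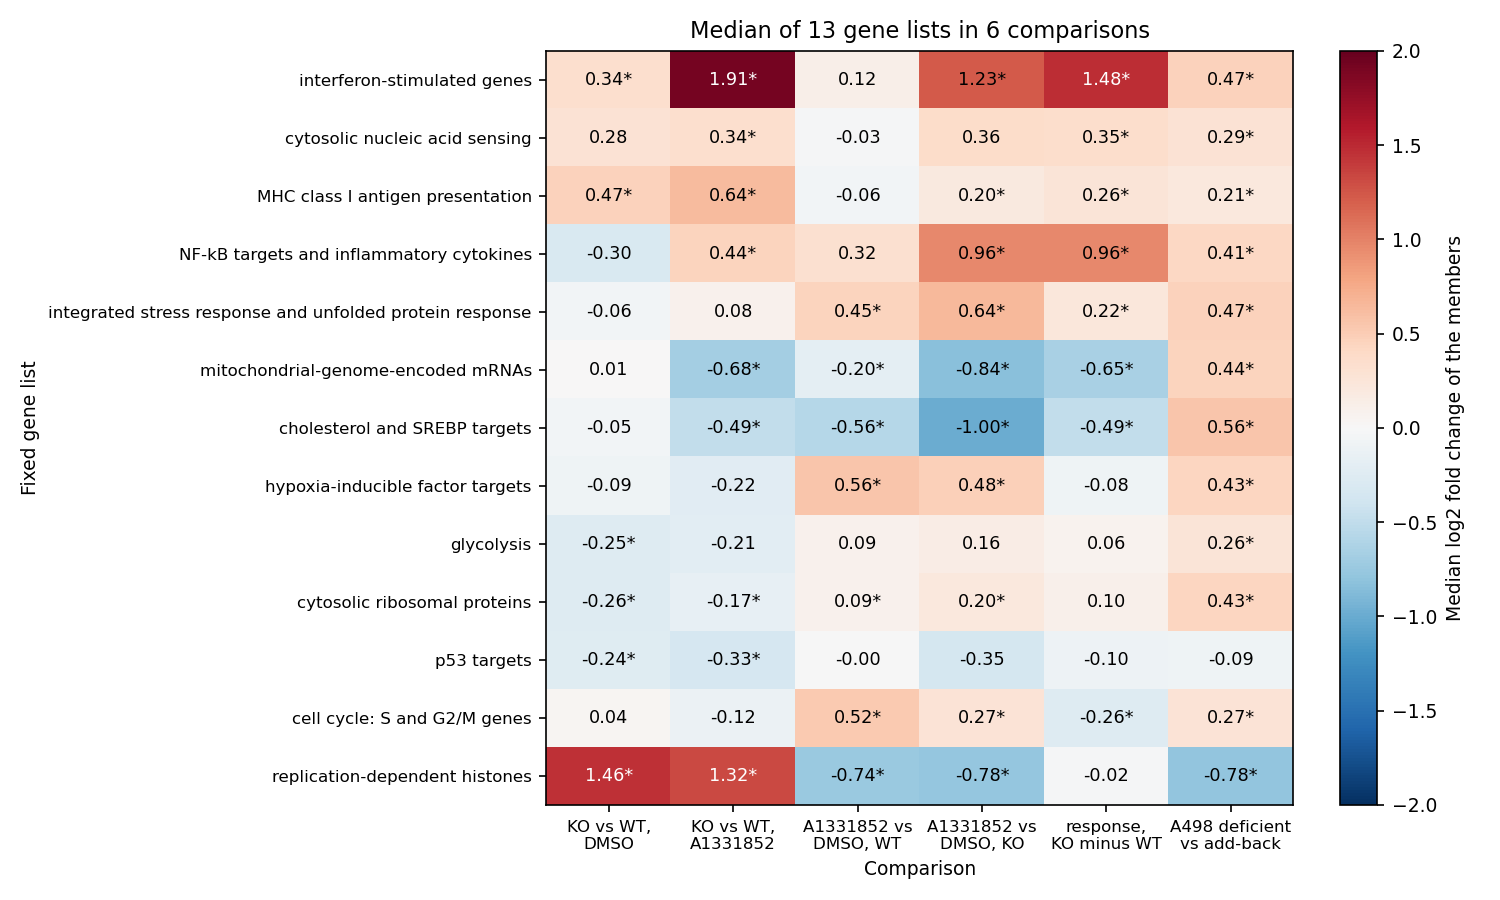
Median log2 change (colour and printed value) of 13 gene lists (vertical axis) in 6 comparisons (horizontal axis); a star marks an adjusted p under 0.05 by camera with the preset correlation. Interferon-stimulated genes have medians of 1.91 for KO against WT in A1331852 and 1.23 for A1331852 against DMSO in KO cells.

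The sixth comparison asked what differs between A498 libraries labelled SETD2 deficient and add-back. SETD2 was at 49.9 ± 6.02 CPM in the deficient and 49.99 ± 12.9 CPM in the add-back libraries (SD, n = 2 each). The log2 change was 0.00 ± 0.17 (adjusted p = 0.991, edgeR), so the transcript level did not distinguish the arms. These counts did not show whether the add-back was a construct that counting by exon missed or whether the arms were other than labelled. As groups, interferon-stimulated genes, SREBP targets, cytosolic ribosomal protein genes and stress response genes were higher in the libraries labelled deficient, though none of these list calls held with an estimated correlation. IFI44L, an interferon-stimulated gene, rose by 2.02 ± 0.14 (adjusted p = 1.89e-07, edgeR) and SCD, the stearoyl-CoA desaturase, by 2.11 ± 0.12 (adjusted p = 2.15e-08, edgeR). BCL2L1 had a change of -0.26 ± 0.12 (adjusted p = 0.13, edgeR; 0.0216 without deficient replicate 1), BCL2L11 rose by 0.82 ± 0.16 (adjusted p = 0.00146, edgeR) and PMAIP1 by 1.51 ± 0.15. BAX, another effector of apoptosis, changed by -0.52 ± 0.18 (adjusted p = 0.0445, edgeR), a call lost without deficient replicate 2 (0.21; log2 -0.18) or add-back replicate 1 (0.102) or 2 (0.0968).

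In A498, 4657 of 15424 genes tested were called by edgeR, 2324 higher and 2333 lower in the libraries labelled deficient, all in batch 3 (2366 and 2256 with DESeq2 size factors, 2022 and 2645 with upper-quartile factors, 2919 and 2782 without deficient replicate 2). BHMT2 (chromosome 5, 79069767 to 79090069), a homocysteine methyltransferase gene, was at least 496-fold higher, with 0 counts in the add-back libraries against a floor of 3 over the group (254-fold and 243-fold without add-back replicate 1 and 2). BASP1 had 2210 counts in deficient and 1 in add-back libraries, a ratio of 2600 (467 to 103000), or 1330 without add-back replicate 1 and at least 424 without replicate 2. EMC10 had 1823 and 1, a ratio of 2150 (385 to 84800), or 1100 and at least 350 without them. HNF4A, a nuclear receptor of kidney and liver epithelium, had 319 and 3, a ratio of 125 (42.5 to 610). The zinc finger genes ZNF429 (chromosome 19, 21496682 to 21556270) and ZNF714 (chromosome 19, 21082159 to 21125270) had 0 counts in deficient libraries and were at least 82.1-fold and 75.6-fold lower there (40.8-fold and 37.5-fold without deficient replicate 1, 41.3-fold and 38.1-fold without 2). ZNF320 changed by -5.96 ± 0.36, ZNF28 by -5.27 ± 0.27 and TINAGL1 by -5.08 ± 0.20. HPCAL4 had 217 counts in add-back and 3 in deficient libraries, a ratio of 61.4 (20.7 to 300). LAMA4, a laminin, rose by 4.68 ± 0.35 and ANPEP, a brush border peptidase, by 2.45 ± 0.14.

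Of 41 interferon-stimulated genes in A498, 20 rose and 2 fell in libraries labelled deficient (26 and 2 adjusted over the list alone). The median was 0.47, with an adjusted p of 3.19e-07 (camera), or 0.291 with an estimated correlation. OASL rose by 1.96 ± 0.16, OAS2 by 1.87 ± 0.17 and IFIT3 by 1.45 ± 0.14. Of 24 cholesterol and SREBP targets, 17 rose and 0 fell (19 and 0 adjusted over the list alone; median 0.56, adjusted p = 5.03e-07, or 0.291 with an estimated correlation). Members included INSIG1 (1.80 ± 0.13) and FASN (0.95 ± 0.13). Of 83 cytosolic ribosomal protein genes, 53 rose and 0 fell (58 and 1 adjusted over the list alone; median 0.43, adjusted p = 8.94e-10, or 0.558 with an estimated correlation). RPL37 changed by 0.87 ± 0.12 and RPL4 by 0.75 ± 0.11. Of 30 integrated stress response genes, 16 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.47, adjusted p = 2.29e-05, or 0.291 with an estimated correlation). Members included DDIT4 (1.91 ± 0.15), PSAT1 (1.70 ± 0.12) and TRIB3 (1.57 ± 0.14). Of 31 hypoxia-inducible factor targets, 15 rose and 3 fell (17 and 3 adjusted over the list alone; median 0.43, adjusted p = 2.36e-04, or 0.291 with an estimated correlation). LOX, which crosslinks collagen, rose by 5.74 ± 0.27, STC2 by 2.16 ± 0.14, HK2 by 1.94 ± 0.17, CA12 by 1.73 ± 0.12 and the lipid droplet gene PLIN2 by 1.70 ± 0.12. Cell cycle genes (12 of 45 rose and 2 fell, 15 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.00201, or 0.502 with an estimated correlation) were also higher. So were mesenchymal genes (14 of 34 rose and 3 fell, 15 and 7 adjusted over the list alone; median 0.28, adjusted p = 0.0119, or 0.502 with an estimated correlation). Another 8 list calls were lost when 1 library was left out, and all 8 with an estimated correlation. For nucleic acid sensing (8 of 20 rose and 2 fell; adjusted p = 0.0424, or 0.502 with an estimated correlation) this was deficient replicate 2 or either add-back replicate (up to 0.112), and IRF7, a transcription factor of interferon genes, rose by 1.18 ± 0.16. For NF-kB targets (12 of 24 rose and 4 fell; adjusted p = 0.0414, or 0.558 so estimated) this was deficient replicate 2 (0.106), and CXCL8, a chemokine gene, changed by 3.46 ± 0.30, CSF1 by 1.18 ± 0.11 and the cytokine gene IL11 by -2.98 ± 0.27. For glycolysis genes (9 of 23 rose and 1 fell; 0.0302, or 0.644) it was deficient replicate 1 or add-back replicate 1 (up to 0.0858), and GAPDH rose by 0.67 ± 0.10. Histones, with a median of -0.78 (0.0118, or 0.502) and H2BC12 at -0.87 ± 0.15, were lost without deficient replicate 1 or add-back replicate 2 (up to 0.192). With a filter at a mean of 50 counts these NF-kB, glycolysis and histone calls were lost (0.123, 0.0634 and 0.64). The count of 4657 fell to 2246 and 2303 without add-back replicate 2 and 1, where the lone add-back library was assumed to vary like the deficient ones, and the estimate of the spread from all 16 libraries gave 2361.

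The last comparison asked whether genes differed in the same direction in 786-O (KO against WT) and A498 (deficient against add-back, as labelled). Of 14325 genes tested in both, 275 were called higher in both 786-O KO cells (DMSO) and A498 libraries labelled deficient against 164.3 expected if the calls were independent (odds ratio 2.03, Fisher's exact p = 7.74e-20). A further 387 were lower in both against 222.2 expected (odds ratio 2.22, Fisher's exact p = 4.19e-32). Another 339 were called in opposite directions against 387.79 expected, so that 66.1% of the 1001 genes called in both had the same direction. The Fisher tests took genes as independent, which they are not, so these p-values can be too small. Across genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.0755 and Spearman rho = 0.129. Examples chosen after their values were seen are the nuclear receptor gene RORB (4.50 in 786-O and 6.89 in A498), the selenium transport gene SELENOP (4.75 and 3.11) and the aromatic amino acid decarboxylase gene DDC (2.59 and 3.09). So are the glutamate receptor gene GRIK2 (2.97 and 2.47) and the aldo-keto reductase gene AKR1B10 (3.26 and 2.07). Lower in both were SARDH, a mitochondrial sarcosine dehydrogenase (-2.50 and -4.53), SYT11 (-5.12 and -2.17) and ASS1, the argininosuccinate synthase (-4.63 and -2.04). With an added log2 threshold of 1, 77 were higher and 67 lower in both. The 662 shared genes fell to 358 and 363 without A498 add-back replicate 2 and 1, and to 370 to 389 without any DMSO library of 786-O.

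**Figure D5:**
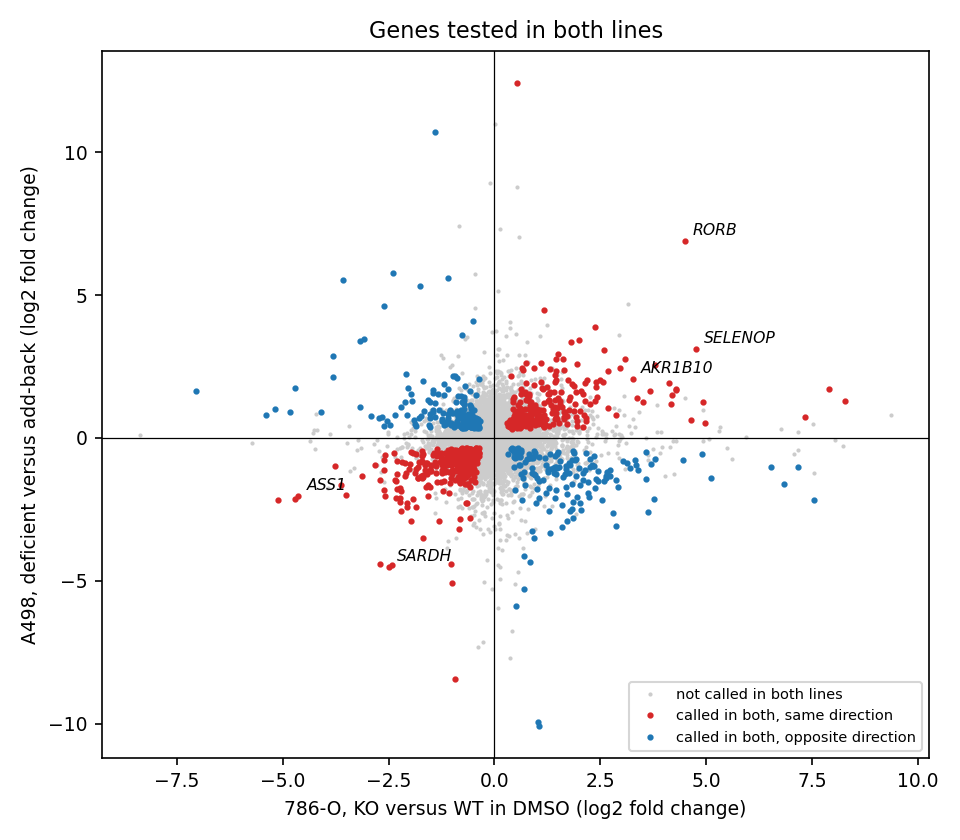
Log2 change of each gene tested in both lines, 786-O KO against WT in DMSO on the horizontal and A498 deficient against add-back on the vertical axis; coloured points are genes called in both. RORB, SELENOP and AKR1B10 are higher, SARDH and ASS1 lower in both.

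The change from WT to KO in 786-O differed from the change between the labelled arms of A498 for 2362 of 17868 genes tested by edgeR, 1093 higher and 1269 lower in 786-O relative to A498. Histone genes (9 of 15 higher and 0 lower, 10 and 0 adjusted over the list alone; median 1.85, adjusted p = 1.88e-06, or 0.0943 with an estimated correlation) differed in the direction of 786-O KO cells. H2BC12 differed by 2.61 ± 0.25 (SE, n = 3 per group in 786-O and 2 in A498). Cytosolic ribosomal protein genes (46 of 83 lower and 0 higher, 57 and 0 adjusted over the list alone; median -0.70, adjusted p = 1.59e-16, or 0.608 with an estimated correlation) differed the other way. RPL11 differed by -1.30 ± 0.20 and RPS24 by -1.24 ± 0.19. Integrated stress response genes were lower too (10 of 30, or 15 and 1 higher adjusted over the list alone; adjusted p = 0.001, or 0.596 with an estimated correlation), ATF4 by -1.40 ± 0.21. So were hypoxia-inducible factor targets (8 of 31, or 10 adjusted over the list alone; adjusted p = 0.001, or 0.821 with an estimated correlation), STC2 by -3.11 ± 0.38. Glycolysis genes (8 of 23, or 10 adjusted over the list alone; adjusted p = 7.13e-04, or 0.0943 with an estimated correlation) were lower, GAPDH by -1.07 ± 0.19. Cholesterol genes were lower as well (3 of 25, or 10 adjusted over the list alone; adjusted p = 0.001, or 0.821 with an estimated correlation). Interferon-stimulated genes were not called as a list (median -0.07, adjusted p = 0.75), 2 of 43 being higher and 3 lower, with IFIT2 at -1.65 ± 0.30. SETD2 differed by -1.24 ± 0.29 (adjusted p = 0.0106, edgeR), a call lost without A498 deficient replicate 2 (0.0782) or add-back replicate 1 (0.0765). The count fell to 1151 and 1194 without add-back replicate 2 and 1, to 1320 and 1564 without deficient replicate 2 and 1, and to 1550, 1557 and 1509 without WT DMSO replicates 1 and 2 and KO DMSO replicate 1. With upper-quartile scaling 59.1% of calls were higher, against 46.3% with TMM, and with an added log2 threshold of 1 the split was 852 higher and 745 lower. More were higher than lower without replicate 3 of WT DMSO (915 and 867) or KO DMSO (904 and 876), KO DMSO replicate 2 (802 and 782) or add-back replicate 1 (612 and 582) or 2 (586 and 565).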

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

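In this part both tests on the SETD2 transcript in KO cells under A1331852 and the test of library scaling were chosen only after that result was seen. The response to A1331852 differed between KO and WT cells of 786-O by a test of the difference itself for 48 genes (edgeR; 0 without KO DMSO replicate 1 or 2, 1186 and 1159 at an unadjusted p under 0.05). The log2 differences were 6.44 for MMP1, 3.97 for DNER, 3.12 for KRT81, 3.02 for SERPINB7, 2.81 for OASL, 2.50 for IFIT2, 2.23 for IFIT3, 2.01 for IFI44 and 1.77 for IL6, and -4.24 for SEMA5B (-4.86 and -4.94 without KO DMSO and KO A1331852 replicate 3), -3.86 for PDZK1, -2.39 for CD24, -2.32 for NCKAP5 and -2.32 for CDH16. Median log2 differences over called lists were 1.48 for interferon-stimulated genes, 0.96 for NF-kB targets, 0.35 for nucleic acid sensing, 0.26 for MHC class I presentation, -0.65 for mRNAs of the mitochondrial genome and -0.49 for cholesterol genes. The medians of 0.16 for mitochondrial ribosomal proteins, -0.26 for cell cycle genes and 0.22 for the integrated stress response belonged to list calls that were lost without 1 library. None of the list calls of this comparison held with an estimated correlation or by directional fry. For mitochondrial ribosomal proteins the call (adjusted p = 0.0147, camera) was lost without WT A1331852 replicate 3, KO A1331852 replicate 1 or KO DMSO replicate 1 (up to 0.92). For cell cycle genes (0.0147) it was lost without WT DMSO 3, WT A1331852 1, KO DMSO 3 or KO A1331852 3 (up to 0.606), and for the stress response (0.0469) without WT DMSO 3, WT A1331852 1, KO DMSO 3 or KO A1331852 2 or 3 (up to 0.404).

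A count of 48 or more genes came from 9 of 100 drawn regroupings of treatment within genotype, the real one included, so chance was not excluded for the count. The highest other count was 2452 genes, several times the real one, which points to a structure of the samples. Of the 8 other regroupings this large, 7 regrouped WT libraries alone, so they kept the response of KO cells (2201 genes) in the difference and did not measure chance alone. The highest was the only 1 of 77 that mixed both genotypes to reach 48, and it set WT DMSO replicates 1 and 2, both of batch 2, with WT A1331852 replicate 3. For the 4 comparisons of 3 libraries with 3, the 10 splits were too few for a share under 0.05, and the real split was the 1 with the most genes in each. The counts were 3001 for KO against WT in DMSO, 4588 in A1331852, and 23 and 2201 for A1331852 against DMSO in WT and KO cells, with 0 as the highest of the other splits in all 4.

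As a group, interferon-stimulated genes responded more to A1331852 in KO than in WT cells. Treatment and batch overlapped in part, but within batch 1 alone the median difference was 1.01 (quartiles 0.556 and 1.62), with 41 of 41 members above 0. All members shared 1 DMSO library per genotype there, so they are not independent replicates of this difference. No single library carried it, since the lowest median with any of the 12 libraries left out was 1.19 (without KO A1331852 replicate 2), and the highest was 1.64. Under 3 library scalings the median was 1.43 to 1.48, but these moved the median of all genes too little (-0.0424 to 0.00684) to test scaling by that median. Scaling shifts all genes of a library alike, so the distance of the list to the median of all genes, at least 1.47, hardly depends on it. That distance is therefore no test of scaling. It shows only that these genes differed from the rest. A greater interferon response of SETD2 KO cells to BCL-XL inhibition may remain as a hypothesis. The reservations are that the list call was lost with an estimated correlation and by directional fry, and that 1 KO and 1 WT population were studied.

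SETD2 was at 29.5, 47.7 and 52.5 CPM in the KO A1331852 libraries, against 28.0 to 30.2 CPM in KO DMSO, and its log2 response in KO cells of 0.57 was called when KO A1331852 replicate 1 was left out (0.79, adjusted p = 0.00707, edgeR). WT cells among KO replicate 3 would need a share of 60.4% to give its SETD2 level. There, 11 genes silent in KO DMSO cells closed a median of -0.876% of the gap between their KO DMSO and WT A1331852 levels. In replicate 2, where 48% would be needed, the median was -0.226%. These values argue against such a mixture. A response to A1331852 that depends on SETD2 may remain an explanation, as the difference between the KO and WT responses had an adjusted p of 0.438 (edgeR) and an upper bound of 1.06 at 2 standard errors. No protein level was measured, and the position of the edit within the transcript was not examined.

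The change in 786-O (KO against WT, DMSO) differed from that in A498 (libraries labelled deficient against add-back) by a test of the difference for 2362 genes. The log2 differences were -1.24 for SETD2, 0.85 for BAK1, 8.15 for RTN1, 3.97 for COL12A1, 2.61 for H2BC12, -6.71 for CDH11, -4.49 for SPATA18, -3.11 for STC2, -1.93 for CSF1, -1.65 for IFIT2, -1.47 for MRPS21, -1.46 for IFIT3, -1.40 for ATF4, -1.30 for RPL11, -1.24 for RPS24 and -1.07 for GAPDH. For EMC10 and BASP1, with a group at 3 counts or fewer, only the adjusted p of 1.48e-10 and 1.63e-09 (edgeR) is given. The SETD2 call was lost without A498 deficient replicate 2 (0.0782) or add-back replicate 1 (0.0765). Median log2 differences over called lists were 1.85 for histones, -0.48 for NF-kB targets, -0.45 for mRNAs of the mitochondrial genome, -0.70 for cytosolic ribosomal proteins, -0.50 for glycolysis, -0.57 for hypoxia-inducible factor targets, -0.60 for the integrated stress response, -0.71 for cholesterol genes and -0.42 for mesenchymal genes. None of these list calls held with an estimated correlation. The call for mitochondrial mRNAs was lost without A498 deficient replicate 2 or add-back replicate 1 (adjusted p up to 0.245, camera). No explanation was tested for this difference, in which line, clone history and the direction of the engineering all differ. The SETD2 transcript did not distinguish the arms of A498 (adjusted p = 0.991, edgeR).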

How the results depend on the processing

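In this part the replicate block within treatment and the fits without replicate 3 of both A1331852 groups were chosen only after the data were seen. The replicate block without that restriction joined numbers across treatments in 786-O, where they did not pair libraries. Of the 186 named gene results tested (the genes shown for both lines were not among them), none with a call turned its direction, but the larger share of calls did: with upper-quartile factors from 44.9% to 53.8% higher (KO against WT in DMSO) and from 46.3% to 59.1% (difference between lines), with DESeq2 size factors from 49.9% to 51.2% (A498), and without KO DMSO replicate 3 to 884 higher and 809 lower (KO against WT in DMSO), among others. Under DESeq2 and under DESeq2 size factors all 186 had the same call. With 1 library left out 1070 of 1190 did, 119 lost a call and 1 gained one (BCL2L1 in A498 without deficient replicate 1, -0.32, adjusted p = 0.0216, edgeR). As the genes were picked preferring calls that held with each library left out, this count does not measure stability. Without a batch term 97 of 130 did and 33 lost a call. With the replicate block 183 of 186 did and 3 gained one: MCL1 in KO against WT in DMSO (-0.40, adjusted p = 0.0181, edgeR), and MCL1 (0.57) and BCL2L1 (0.72) for A1331852 in KO cells. SETD2 kept its side of the threshold in 47 of 50 values with 1 library left out and in 6 of 7 with the block (gained for A1331852 in KO cells, 0.66).

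For KO against WT in DMSO (3001 genes) the counts were 1273 with the log2 threshold of 1, 4862 with the block, 4646 with the block within treatment, 1490 without a batch term, 7446 from the compared libraries alone, 9276 from batch 2 alone, and 1614 to 1777 with 1 library left out. For KO against WT in A1331852 (4588) they were 1905 with the log2 threshold, 2489 without a batch term and 2287 from the compared libraries alone. For A1331852 in WT cells (23) they were 909 without a filter, 415 with DESeq2, 2831 with the block and 6 without a batch term. They were 214 without both replicates 3, and 0 (596 at an unadjusted p under 0.05, fewer than by chance) to 64 with 1 library left out. In KO cells (2201) they were 1282 with the log2 threshold, 4311 with the block, 85 from batch 1 alone, 5227 without both replicates 3, and 781 to 2602 with 1 library left out. For the difference of responses (48) they were 647 without a filter, 371 with DESeq2, 30 after thinning, 334 with the block and 294 with the block within treatment. They were 7 without a batch term, 929 without both replicates 3, and 0 (1186 unadjusted) to 5.0e+02 (rounded) with 1 library left out.

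For A498 (4657) the counts were 1583 with the log2 threshold, 2361 with the spread of all 16 libraries, and 2246 to 6272 with 1 library left out. For the difference between lines (2362) they were 3742 with the block and 1151 to 1782 with 1 library left out. Shared calls (662) were 144 with the log2 threshold, 1199 with the block, 348 without a batch term and 358 to 792 with 1 library left out. Called lists numbered 0 in all 7 comparisons with an estimated correlation, against 6, 10, 12, 16, 9, 15 and 9 with the preset one. In the same order they numbered 5, 11, 0, 10, 0, 8 and 6 by directional fry, and 21, 24, 3, 20, 7, 24 and 20 by mixed fry. The 12 lists of A1331852 in WT cells became 6 with the block, 7 without a batch term and 7 to 12 with 1 library left out. The 16 lists in KO cells became 10 with the block, 8 without a batch term and 9 to 17 with 1 library left out. The log2 threshold makes fewer calls by construction, and the cause was not tested for the other alternatives. At the smallest total of 14172118 counts, 3 counts over a group was the floor.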

Other observations

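In this part the tests on whole regions within each line and on the number of genes detected were chosen only after the result was seen. Genes of the BCL-2 family did not change as lists in any comparison (camera), but single members did. Of 11 pro-death members tested in 786-O, 2 rose and 2 fell with A1331852 in KO cells (median 0.05, adjusted p = 0.845). Of 5 pro-survival members, 2 rose and 1 fell (median 0.40, adjusted p = 0.154). Epithelial and renal tubular genes went both ways: under A1331852, 7 of 21 were higher and 8 lower in KO than in WT cells (median 0.14, adjusted p = 0.838), and in A498 12 of 26 were higher and 3 lower in libraries labelled deficient (median 0.03, adjusted p = 0.25). Readers, writers and erasers of H3K36 methylation, autophagy, caspases and mitochondrial dynamics were also not called in any comparison. For KO against WT under A1331852, 2 of 23, 7 of 29, 2 of 26 and 5 of 27 members of these lists rose, and 5, 4, 2 and 3 fell. Among cell type markers, 3 leukocyte genes were tested in 786-O, and their list was called after A1331852 in WT (median 1.78, adjusted p = 0.00221, camera) and KO cells (median 2.14, adjusted p = 0.0187). Both calls were lost with 1 library left out, among others WT A1331852 replicate 1 (up to 0.143 in WT) and KO DMSO replicate 3 (up to 0.405 in KO). They were also lost with an estimated correlation (0.482 and 0.341), without a batch term (0.118 and 0.119) and without replicate 3 of both A1331852 groups (0.205 and 0.137). The list of 5 fibroblast and pericyte genes was called after A1331852 in KO cells (median -0.93, adjusted p = 0.0309), with 0 members above 0 and 1 called. This was lost without KO DMSO replicate 3 or KO A1331852 replicate 1 or 3 (up to 0.175), with an estimated correlation (0.341), with a replicate block (0.0592), without a batch term (0.115), with a filter at a mean of 50 counts (0.0683) and without replicate 3 of both A1331852 groups (0.0708).

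A few genes were at 5 CPM or more in 1 arm and at 0.1 CPM or less in the other, 8 in 786-O (among them RTN1, POU3F3, SLAIN1, SRGN and C1QTNF1) and 12 in A498 (among them BHMT2, BASP1, EMC10, HNF4A, ZNF429, ZNF714 and HPCAL4). Loss of SETD2 switching the same genes in both lines would have given shared genes, and 0 were shared, but the SETD2 transcript did not distinguish the arms of A498 (adjusted p = 0.991, edgeR), so this excluded nothing. Loss or silencing of whole regions was tested first on 40 nearest neighbours, of which 0% were switched by that definition. A second test, chosen because zinc finger genes beside switched ones fell strongly without reaching 0.1 CPM, asked whether neighbours were called the same way by at least 2-fold. In 786-O 0% of 16 were, which argues against whole regions there, although differences between cell populations may remain. In A498 45.8% were (11 of 24, against 4.1% to 5.64% of all protein-coding genes tested). This share comes from the same data that prompted the test, so it is no independent support. Loss or silencing of whole regions, or differences between cell populations, may remain as explanations in A498. Of the 4 genes off in libraries labelled deficient, 3 were zinc finger genes on chromosome 19.

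At an equal depth of 14172118 counts, KO libraries held counts for more gene names than WT libraries of the same treatment and batch. The ranges were 22593 to 23851 against 21039 to 22722 in DMSO and 22897 to 23303 against 21636 to 22343 in A1331852. With genotype shuffled within treatment (exact permutation test, two-sided, 400 arrangements, smallest possible p = 0.005) the p was 0.01. Shuffled within treatment and batch (240 arrangements) it was 0.00833, the smallest possible, and KO was above WT in 6 of 6 pairs of the same number. In A498 the ranges were 22593 to 23113 in libraries labelled deficient and 23047 to 23340 in add-back. That loss of SETD2 lets more genes be transcribed may be a hypothesis for 786-O, but 1 KO population cannot separate it from a difference between clones.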
